A study of Homo sapiens with 36 samples.

How the data were processed

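RNA-seq was measured in 36 libraries of HepG2-IGF1R-KO cells, a human hepatoma line in which the gene of the IGF-1 receptor was targeted. Per the labels' protocols, RNA was isolated with a column kit and DNase, poly-A RNA was selected, and strand-specific libraries were made. The deposited table gives expected counts, that is estimated read counts per Ensembl gene that need not be whole, with no scaling to a common total. Per the submitters' processing notes, STAR, Salmon and the genome build GRCh37 were used; versions, annotation release, counting settings and any filter are not given in the sources used here. Of all values in the table, 15.5% were not whole, and the counts were rounded to whole numbers before testing. The table holds 57771 genes, of which 24214 were at 0 in all libraries. Gene symbols came from a GRCh38 annotation through the Ensembl identifier, which gave a current symbol to 51994 genes (90.0%). No coordinates are printed, since the builds differ. Where paralogs share sequence, as in the AKR1C family, the split of reads between them by the authors' counting cannot be checked.

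Each library was assigned by its title to 1 of 4 groups of 9 libraries, and the labels call the 9 biological replicates. The labels also give a batch date. The 22 April batch held 4 untreated and 5 insulin-stimulated libraries in normal medium and 4 and 3 in insulin-resistant medium. The 11 April batch held 2, 2, 2 and 6, and the 24 May batch 3, 2, 3 and 0. Library totals were 26.6M to 116.8M counts (median 64.6M), with a median of 103.0M in the 24 May batch against 64.1M and 61.6M in the batches of 22 and 11 April. At these totals a count of 0 allows up to 3 counts, and counting error is small beside the spread between libraries for most genes named here. LEAP2 had 40 to 222 counts per library.

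All 36 libraries entered a model with a coefficient per group and a batch term, fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling to the reference library the tool chooses, filterByExpr, robust quasi-likelihood F-test), and p-values were adjusted by Benjamini-Hochberg over the 17983 genes tested. The threshold was an adjusted p under 0.05. Standard errors are those of the log2 fold changes, and group levels of genes are TMM-scaled CPM given as mean ± SD. The median CPM of the stromal list and the hepatocyte level are CPM of the library total, without TMM factors. The 24 gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 24 lists. LEAP2 was also tested with exact two-sided permutation tests of log2 CPM, adjusted over 4 comparisons. These tests, the lists, the rule for named genes and the alternatives given first below were set before the data were examined. The rule names 23 key genes, of which 22 were measured, the 10 genes with the largest rise and the 10 with the largest fall among those called at a mean of at least 5 CPM, and up to 4 members per list with the smallest adjusted p. Not all genes that meet the rule are named, and some results of such genes are not reported here.

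The lists cover gluconeogenesis and FOXO1 targets, the insulin receptor pathway, fatty acid synthesis, cholesterol synthesis, glycolysis, fatty acid oxidation, lipid droplets and lipoproteins, LXR targets and bile acid enzymes, ATF4 and amino acid synthesis, endoplasmic reticulum chaperones, the cell cycle, ribosome biogenesis, secreted liver proteins, hepatocyte identity, inflammation, NRF2 targets, hypoxia, MAPK feedback, p53 targets, the respiratory chain, and markers of stromal, endothelial, leukocyte and cholangiocyte cells. Of their 502 entries, 496 were found in the table, and the others were not analysed here.

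Replicates of a group were compared before use. No pair agreed within sampling noise, since the lowest chi-square per gene was 4.61. Replicates 1 to 3, 4 to 6 and 7 to 9 of a group form 3 sets, called triplets here, whose library names carry consecutive position codes. The alternatives set beforehand were DESeq2 1.42.0 and its size factors, other filters on low counts, no batch term, a replicate block, a plate-set term, surrogate variables (sva 3.50.0), fits of only the groups compared, fits within or without a batch, a minimum fold change of 1.2, and leaving out each library. Added after seeing the data were fits without 6 libraries whose stromal marker list had a median under 1 CPM, scaling to 22 hepatocyte genes, fits with a triplet as the unit, TMM factors averaged over every reference library, and fits within the 11 April and 24 May batches.

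The count test was also tested, after its first results had been seen, on simulated counts with known changes, drawn with independent libraries from the means and dispersions of the real ones. In the simulation of the insulin effect in normal medium with 36 libraries and 17983 genes, 46.3% of those changed 1.5-fold, 68.7% of those changed 2-fold and 81.8% of those changed 4-fold were called in the right direction, and 7 of 17759 unchanged genes were called. In that of the insulin effect in insulin-resistant medium the shares were 49.3%, 71.6% and 78.8%. In that of the medium effect in untreated cells they were 47.8%, 76.1% and 87.9%, and in insulin-stimulated cells 44.8%, 64.2% and 89.4%. The difference of insulin effects was not simulated. Real libraries cluster by triplet, so the shares recovered and the few false calls need not hold for them. Figures and the permutation tests used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.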

Results

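Transcript levels were measured by RNA-seq in HepG2-IGF1R-KO cells under 4 conditions, with 9 libraries each. Cells were kept in normal or insulin-resistant medium, and in each medium were left untreated or given 3 nM human insulin for 18 h. The insulin-resistant medium held 1 nM insulin, 0.5 mM fatty acids (palmitic, linoleic and oleic) and 20 mM glucose for 72 h. The labels do not say whether that insulin was removed before untreated cells were harvested, so in this medium the comparison may be of 3 nM against 1 nM insulin. The design asks how these cells respond to insulin in either medium, and the series title names LEAP2, a liver-derived peptide that antagonises the ghrelin receptor. Library totals were 59.9M to 116.8M and 30.6M to 111.9M counts for untreated and insulin-stimulated cells in normal medium. They were 26.6M to 101.8M and 60.3M to 73.3M counts in insulin-resistant medium.

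IGF1R, the targeted gene, was transcribed in every library. Its level was 112 ± 23.8 CPM and 93.6 ± 11.1 CPM in untreated and insulin-stimulated cells in normal medium, and 89.4 ± 19.1 CPM and 99.7 ± 17.7 CPM in insulin-resistant medium (SD, n = 9 each). All libraries carry the knockout label and there is no unedited control, so gene-level counts do not check the edit. The log2 fold change of IGF1R with insulin in normal medium was -0.28 ± 0.12 (edgeR adjusted p = 0.0799). It passed the threshold at -0.35 with TMM factors averaged over every reference library and in 28 of 36 fits that left out 1 library (-0.42 to -0.34). It also passed at -0.32 (edgeR adjusted p = 0.0223) without the 6 libraries low in stromal transcripts. INSR, the insulin receptor, stood at 63.9 ± 5.36, 57.2 ± 11.5, 48.8 ± 11 and 39.6 ± 2.62 CPM in the same order.

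Collagen and other stromal transcripts were abundant in 30 libraries and near absent in 6. COL1A1, a fibrillar collagen of mesenchymal cells, was at 7170 to 35800 CPM in the 30 and at 0.742 to 1.6 CPM in the 6. COL1A2 was at 6260 to 19300 CPM against 0 to 0.0261 CPM, and COL3A1 at 669 to 4560 CPM against 0 to 0.117 CPM. The median over the stromal marker list was 186 to 670 CPM in the 30 and 0.0163 to 0.0788 CPM in the 6, which were replicates 4 to 6 of insulin-stimulated cells in normal medium and replicates 1 to 3 of untreated cells in insulin-resistant medium. The 30 libraries were not alike. FN1 was at 33200 to 42160 CPM in untreated replicates 7 to 9 of either medium and stimulated replicates 4 to 9 in insulin-resistant medium. In every other library it was at most 17110 CPM. Fits without the 6 libraries keep this difference, which is spread unevenly over the groups and absent from stimulated cells in normal medium. The level of 22 hepatocyte genes, relative to all 36 libraries, was 1.6 to 1.84 in the 6 and 0.605 to 1.68 in the 30. By group it was 1.2 ± 0.26 and 1.14 ± 0.47 in normal medium, untreated and stimulated, and 1.18 ± 0.45 and 0.731 ± 0.035 in insulin-resistant medium (SD, n = 9). Libraries of a triplet resembled one another. Their deviations from the mean of all 36 libraries had a median correlation of 0.936 over 36 pairs. Over the 108 other pairs within groups the median was 0.2135. Among stimulated cells there were exceptions. In insulin-resistant medium, replicates 4 to 6 correlated with replicates 7 to 9 at 0.891 to 0.952, and in normal medium replicate 2 correlated with its own triplet at 0.49 and 0.516. Levels are those of whole libraries, so where stromal transcripts are present these counts cannot assign a change to the hepatoma cells alone. The p-values below treat the 9 libraries of a group as independent, and values without the 6 libraries, a choice made after seeing the data, stand beside the number of genes called in each comparison.

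**Figure D1:**
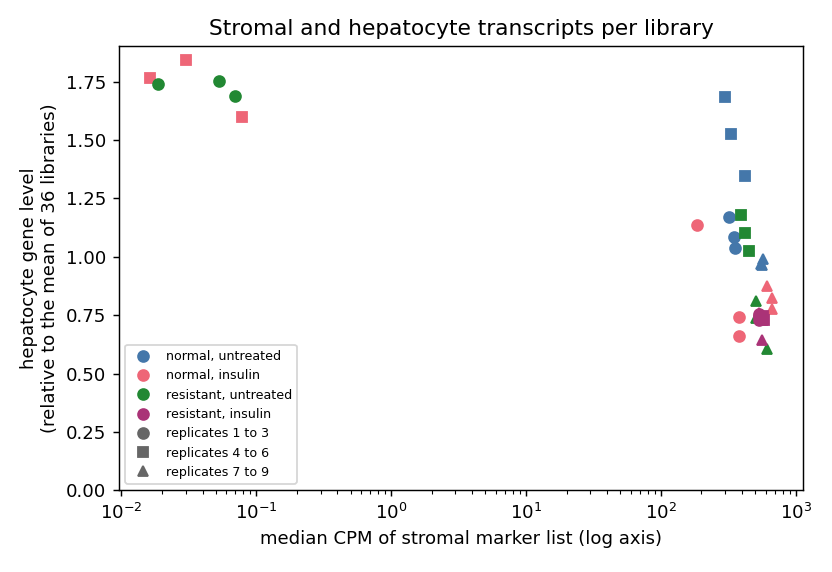
Each point is 1 of 36 libraries, with the median CPM of the stromal marker list on a log x axis and the level of 22 hepatocyte genes relative to the mean of all libraries on the y axis; colour gives the group and shape the replicate triplet. The 6 libraries at the left lie under 0.0788 CPM and the other 30 lie at 186 CPM or above.

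In normal medium, insulin lowered G6PC1 and PCK1, which act in hepatic glucose output. G6PC1, the catalytic subunit of glucose-6-phosphatase, fell from 3.99 ± 0.431 to 0.114 ± 0.0621 CPM (SD, n = 9), a log2 fold change of -5.09 ± 0.32 (SE), with no overlap between the ranges of 3.39 to 4.62 and 0.0199 to 0.225 CPM. PCK1, which catalyses an early step of gluconeogenesis, fell by 0.87 on the log2 scale. FST (follistatin) fell by 1.88, HP (haptoglobin) by 2.34 and SPTLC3, a subunit of serine palmitoyltransferase, by 2.47. EREG, a ligand of the EGF receptor, rose with a log2 fold change of 3.71 ± 0.25, ANGPTL8, an inhibitor of lipoprotein lipase, with 2.22 ± 0.20, and JAG1, a Notch ligand, with 2.03 ± 0.18.

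Gene groups of protein synthesis rose with insulin in normal medium. All 24 measured members of the ribosome biogenesis and MYC target list rose, and 24 also when adjusted over the list alone, with log2 fold changes of 1.23 for RRP12, 1.11 for RRP9 and 1.02 for DKC1 (camera adjusted p = 8.19e-17, and adjusted p = 0.252 with an estimated correlation). Of 22 endoplasmic reticulum chaperone genes 19 rose and none fell (19 adjusted over the list alone), among them SDF2L1 (2.03), MANF (1.76) and HYOU1 (1.93), with a camera adjusted p of 5.03e-16 and an adjusted p = 0.252 with an estimated correlation. Of 24 genes of the ATF4 and amino acid synthesis list 18 rose (19 adjusted over the list alone), including PPP1R15A (1.47), SHMT2 (0.74) and CEBPB (1.31; camera adjusted p = 2.64e-07, and adjusted p = 0.273 with an estimated correlation). Of 20 NRF2 targets 12 rose, such as AKR1B10 (1.96) and GCLC, which makes the glutathione precursor (1.54), and of 20 MAPK feedback genes 10 rose, such as PHLDA1 (1.63) and DUSP6 (0.82). Adjusted over the list alone, 13 and 11 rose, and camera adjusted p were 0.000209 and 0.0025, each with an adjusted p = 0.252 with an estimated correlation. The fatty acid oxidation list had 10 of 23 members lower and 2 higher (11 and 3 adjusted over the list alone), with CPT2 at -0.40, CREB3L3 at -1.28 and a median of -0.21 that turned to 0.22 only when the 6 libraries were left out and the rest scaled to hepatocyte genes (camera adjusted p = 0.00495, and adjusted p = 0.273 with an estimated correlation). The gluconeogenesis and FOXO1 target list had 6 of 21 members lower and 3 higher (the same counts adjusted over the list alone), with BCL6 at -0.58 among the lower (camera adjusted p = 0.0228, and adjusted p = 0.273 with an estimated correlation); its median of -0.07 turned to 0.02 when scaled to hepatocyte genes. Without the 6 libraries the ribosome biogenesis, chaperone, ATF4, NRF2 and MAPK feedback lists had 23, 19, 15, 9 and 8 members higher, with 1 lower in the ATF4 and 1 in the NRF2 list. The fatty acid oxidation list then had 12 lower and 1 higher, and the gluconeogenesis list 10 lower and 2 higher. IGFBP1, which insulin is known to repress, went the other way at 0.72 ± 0.23 (edgeR adjusted p = 0.0137). It did not pass the threshold without the 6 libraries (0.26 ± 0.16). The call was also lost at 0.35 to 0.61 without any 1 of untreated replicates 4, 6, 7 and 9 or stimulated replicates 2, 4, 5 and 6 in normal medium or untreated replicate 6 in insulin-resistant medium. PLIN2, the lipid droplet coat protein, rose by 1.11 and SREBF1 by 0.43. FASN, the fatty acid synthase, was at 0.42 ± 0.15 (edgeR adjusted p = 0.0248). It did not pass at 0.03 ± 0.09 without the 6 libraries, at 0.35 with averaged TMM factors, or at 0.21 to 0.37 without 1 library, except where that was untreated replicate 1 or 3 or stimulated replicate 1, 3, 7, 8 or 9 in normal medium. The median log2 fold change of the stromal markers in this comparison was -0.65 and that of the hepatocyte identity genes 0.04 (-0.03 with averaged TMM factors), and without the 6 libraries they were -0.20 and -0.30.

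With edgeR's quasi-likelihood test at an adjusted p under 0.05, 4484 genes were higher and 1843 lower of 17983 (70.9% higher). Without the 6 libraries 2802 were higher and 3294 lower of 18230. TMM scales to 1 reference library, and 35 of 36 possible references gave lower values here than the default one, with shifts down to -0.12 on the log2 scale. With TMM factors averaged over all references, also chosen after seeing the data, 3419 genes were higher and 2459 lower (58.2% higher). With DESeq2's size factors the split was 3452 and 2434, and scaled to hepatocyte genes, which raised the median of all genes by 0.11, 3304 and 1155, or 10503 and 1133 with the 6 libraries also left out (a shift of 0.37). Within the 22 April, 11 April and 24 May batches 950, 866 and 6058 genes were called, and with each triplet summed to 1 sample 711 were. On 24 May this sets a single untreated triplet against stimulated replicates 2 and 4, and replicate 4 is 1 of the 6 libraries. The count of 6058 therefore cannot separate insulin from differences between triplets or in stromal transcripts.

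**Figure D2:**
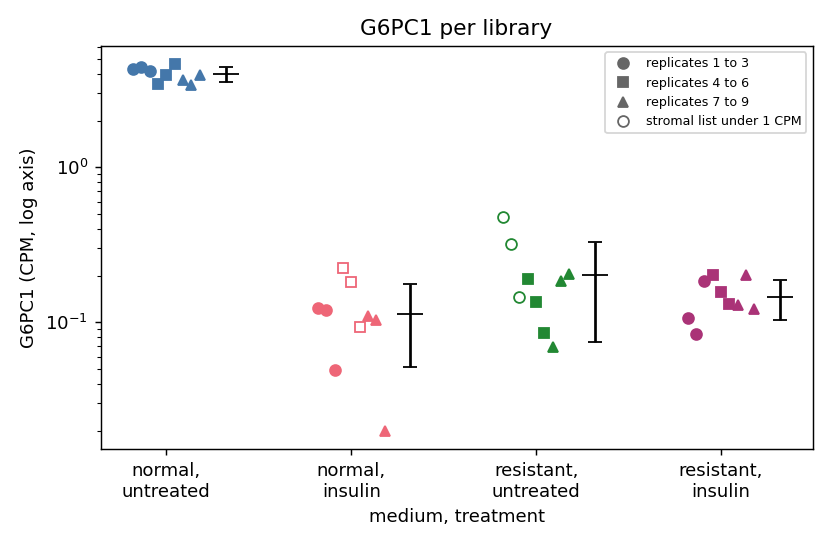
G6PC1 in CPM on a log axis for each library, by medium and treatment; shapes mark replicate triplets, open symbols the 6 libraries with a stromal list median under 1 CPM, and bars the mean ± SD of 9 libraries. Untreated cells in normal medium lie between 3.39 and 4.62 CPM, and the highest library of the other groups is at 0.474 CPM.

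In insulin-resistant medium, insulin changed no gene past the threshold with edgeR, although 4490 genes had an unadjusted p under 0.05 and DESeq2 called 49 higher and 36 lower. G6PC1 was already low there, at 0.201 ± 0.126 CPM untreated and 0.146 ± 0.0422 CPM with insulin (SD, n = 9), and its log2 fold change was -0.41 ± 0.32 (edgeR adjusted p = 0.424), or 0.01 without the 6 libraries. PCK1 was at -0.57 ± 0.18 (edgeR adjusted p = 0.0995). RELB, GDF15 and FOXA3 were at -0.56, -0.67 and -0.63, also with an edgeR adjusted p of 0.0995. These 4 genes passed the threshold without untreated replicate 7 or without untreated replicate 9 in this medium. Without the 6 libraries PCK1 was at -0.13 (edgeR adjusted p = 0.937). RELB, GDF15 and FOXA3 were then at -0.39, -0.34 and -0.24, each with an edgeR adjusted p of 0.915. No member of any of the 24 lists was called over all genes. Adjusted over the list alone, 21 of 23 hepatocyte identity genes, 13 of 19 inflammation genes and 11 of 16 LXR and bile acid genes were lower. The hepatocyte list had a median of -0.50 (camera adjusted p = 3.04e-09, and adjusted p = 0.368 with an estimated correlation), the inflammation list -0.51 (2.91e-06, and adjusted p = 0.287 with an estimated correlation) and the cholesterol synthesis list -0.24 (1.45e-06, and adjusted p = 0.377 with an estimated correlation). The stromal marker list had a median of 0.49, and without the 6 libraries the stromal and hepatocyte medians were -0.31 and -0.05. The cholesterol synthesis median was then 0 (camera adjusted p = 0.853), the LXR median -0.05 (camera adjusted p = 0.108) and the inflammation median -0.11 (camera adjusted p = 0.00324, and adjusted p = 0.63 with an estimated correlation). The hepatocyte list had a camera adjusted p of 0.123 without the 6. Scaling to hepatocyte genes raised the median of all genes by 0.35 and turned the cholesterol synthesis median to 0.20 and the LXR median from -0.40 to 0.09. The inflammation median became -0.02. The hepatocyte median became 0, which follows from the scaling itself, since it uses 22 genes of that list.

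The count of 0 depended on the model: 4012 genes were called when only the 2 groups were fitted, 2063 without the batch term, 4481 with a plate-set term in place of the batch (4875 beside it), 3065 with surrogate variables, 2008 without replicate 7 of the untreated cells in this medium and 965 without their replicate 9. Without the 6 libraries 0 genes were called, also when only the 2 groups were fitted or the batch term was dropped, and 0 were called within the 22 April and the 11 April batch, while the 24 May batch holds no insulin-stimulated library in this medium.

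The response to insulin differed between media for many genes. G6PC1 had a difference of log2 fold changes, resistant minus normal medium, of 4.68 ± 0.44 (SE), EREG of -4.27 ± 0.33, ANGPTL8 of -2.92 ± 0.28 and PLIN2 of -1.41 ± 0.17. FST and HP differed by 1.70 ± 0.15 and 1.89 ± 0.26. In untreated cells the medium alone had already moved G6PC1 by -4.37 and FST by -2.30. With few counts left for G6PC1 to lose, its difference does not by itself show a weaker response. Of 24 ribosome biogenesis genes, which rose in normal medium, 21 had a difference below 0 (22 adjusted over the list alone), such as RRP12 (-1.48) and NOP56 (-1.56), with a camera adjusted p of 4.5e-17 and an adjusted p = 0.311 with an estimated correlation. So did 19 of 22 chaperone genes (20 adjusted over the list alone), such as SDF2L1 (-2.24) and MANF (-1.96; camera adjusted p = 1.32e-14, and adjusted p = 0.311 with an estimated correlation). In the ATF4 list 15 of 24 did (18 adjusted over the list alone), such as PPP1R15A (-1.42) and CEBPB (-1.60; camera adjusted p = 1.81e-06, and adjusted p = 0.449 with an estimated correlation). The medians of these 3 lists were -1.09, -1.17 and -0.61, and -0.63, -0.83 and -0.60 without the 6 libraries. The direction of the lipid synthesis lists depended on those libraries and on the scaling. The cholesterol synthesis list had 11 of 25 members below 0 and 1 above with all 36 libraries, and 1 below and 13 above without the 6. Its median was -0.33 and 0.23 in these fits, and scaled to hepatocyte genes it was 0.08 and -0.14. The fatty acid synthesis list had medians of -0.24 and 0.19, and of 0.15 and -0.18 with that scaling. The stromal median was 1.10 and the hepatocyte median -0.55 with all libraries, and -0.15 and 0.29 without the 6.

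By edgeR, the log2 fold change in insulin-resistant medium minus that in normal medium was above 0 for 1119 genes and below 0 for 4233, whichever way insulin moved them, and without the 6 libraries 2266 and 1709. With averaged TMM factors the split was 1815 and 3303, and with DESeq2's size factors 1840 and 3252. Scaled to hepatocyte genes, which raised the median of all genes by 0.26, it was 1013 and 1087, and with that scaling and the 6 libraries left out, which shifted that median by -0.34, 846 and 6874. Within the 22 April and 11 April batches 4 and 636 genes were called, and with summed triplets 5.

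**Figure D3:**
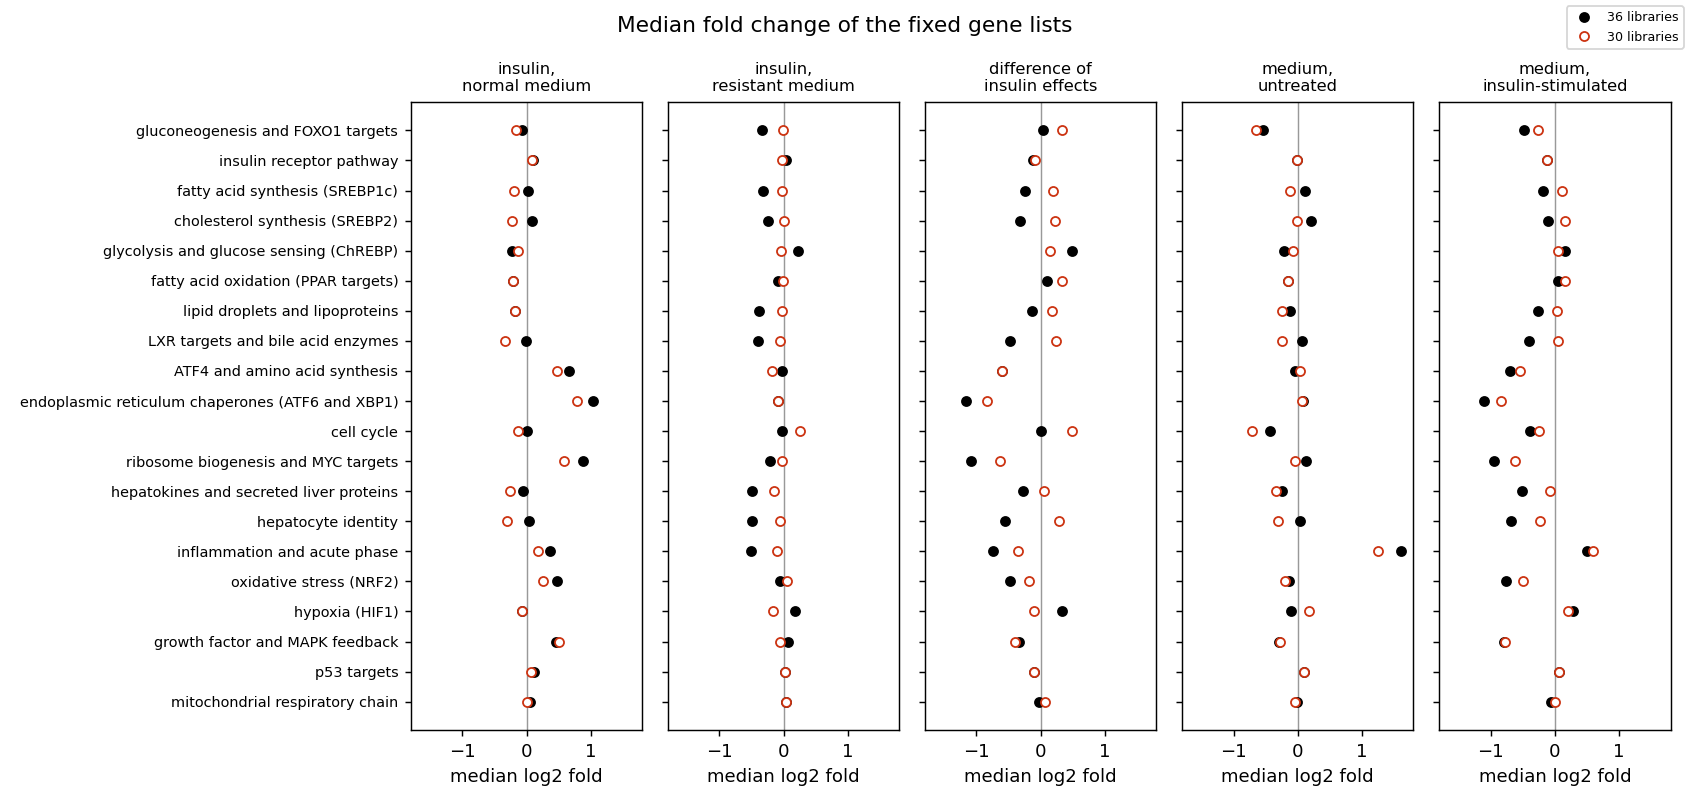
Median log2 fold change of 20 gene lists in the 5 comparisons, with all 36 libraries (filled) and without the 6 libraries low in stromal transcripts (open). The ribosome biogenesis list is at 0.88 for insulin in normal medium, -0.22 for insulin in insulin-resistant medium (0.21 scaled to hepatocyte genes) and -0.94 for medium in insulin-stimulated cells.

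In untreated cells, insulin-resistant medium raised inflammatory transcripts and lowered gluconeogenic ones. The chemokine CXCL8 rose with a log2 fold change of 4.32 ± 0.22 (SE), the adhesion molecule ICAM1 with 2.95 ± 0.16, the apoptosis inhibitor BIRC3 with 3.32 ± 0.19 and the NF-kB subunit RELB with 1.84 ± 0.11. Of 19 inflammation genes 12 rose and 2 fell (13 and 2 adjusted over the list alone), with a camera adjusted p of 1.09e-11 and an adjusted p = 0.0268 with an estimated correlation. PTAFR, the receptor of platelet-activating factor, rose with 4.72 ± 0.19, the protease CTSS with 4.10 ± 0.17 and the ubiquitin-like modifier UBD with 3.44 ± 0.21. Of 21 gluconeogenesis and FOXO1 target genes 11 fell and 1 rose, the same counts when adjusted over the list alone (camera adjusted p = 1.1e-07, and adjusted p = 0.0193 with an estimated correlation). Among them, G6PC1 fell by 4.37, PCK1 by 1.30, IGFBP1 by 1.30, the transcription factor KLF15 by 2.11 and BCL6 by 0.96.

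Lipid droplet genes PLIN2 and CIDEC rose with log2 fold changes of 0.71 ± 0.12 and 1.2 ± 0.18 in this comparison, while the lipid droplet and lipoprotein list as a whole had 2 members higher and 4 lower of 19, the same counts adjusted over the list alone (camera adjusted p = 0.617), with a median of -0.12 that turned to 0.14 when scaled to hepatocyte genes. SREBF1 was at 0.23 ± 0.08 (edgeR adjusted p = 0.0234) and did not pass the threshold without the 6 libraries (0.16 ± 0.06). The call was also lost at 0.20 to 0.21 without 1 of untreated replicates 1 and 2 in normal or 2 and 3 in insulin-resistant medium. Among secreted proteins, the iron hormone HAMP fell by 2.96, and ANGPTL8 rose with 1.91 ± 0.20. The fibrinogen chains FGA, FGB and FGG fell by 1.38, 1.09 and 1.01. Of 25 cell cycle genes 5 fell (7 adjusted over the list alone), including CDT1 at -0.72, with a camera adjusted p of 0.0077 and an adjusted p = 0.927 with an estimated correlation, and 16 fell without the 6 libraries. Of 9 cholangiocyte markers 4 rose (4 adjusted over the list alone), such as KRT19 (1.09) and GGT1 (1.40; camera adjusted p = 0.0348, and adjusted p = 0.0724 with an estimated correlation). The stromal median was -0.20 (0.26 scaled to hepatocyte genes) and the hepatocyte median 0.03, and without the 6 libraries 0.41 and -0.31.

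By edgeR, 2385 genes were higher and 1551 lower, and without the 6 libraries 1948 and 2918. Scaled to hepatocyte genes, which raised the median of all genes by 0.23, the split was 3281 and 429, and with the 6 libraries also left out (a shift of 0.51) 12539 and 462. Within the 22 April, 11 April and 24 May batches 611, 375 and 1808 genes were called, and with summed triplets 485. On 24 May this sets a single triplet of each group against the other, so that count cannot separate the medium from differences between triplets.

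In insulin-stimulated cells, insulin-resistant medium went with lower transcripts of protein synthesis and stress pathways. All 24 ribosome biogenesis genes fell, and 24 when adjusted over the list alone, with MYC at -1.66 and DKC1 at -1.15 (camera adjusted p = 9.18e-18, and adjusted p = 0.14 with an estimated correlation). Of 22 chaperone genes 20 fell (20 adjusted over the list alone), with HSPA5, the main chaperone of the endoplasmic reticulum, at -1.96 (camera adjusted p = 3.03e-14, and adjusted p = 0.125 with an estimated correlation). Of 24 ATF4 list genes 17 fell (17 adjusted over the list alone), with DDIT3 at -2.04 (camera adjusted p = 5.09e-08, and adjusted p = 0.286 with an estimated correlation). Of 20 NRF2 targets 15 fell (16 adjusted over the list alone), with GCLC at -1.95 and AKR1C2, whose reads may be shared with its paralogs, at -3.23 (camera adjusted p = 1.24e-06, and adjusted p = 0.125 with an estimated correlation). Of 20 MAPK feedback genes 15 fell (16 adjusted over the list alone), with SPRY4 at -1.57 and DUSP6 at -1.03 (camera adjusted p = 2.5e-05, and adjusted p = 0.125 with an estimated correlation). Inflammation genes stood higher here too, with 11 of 19 up and 2 down, as when adjusted over the list alone (camera adjusted p = 5.12e-05, and adjusted p = 0.254 with an estimated correlation). BIRC3 rose with 2.45 ± 0.19, TNFAIP3 with 2.07 ± 0.17 and ICAM1 with 1.68 ± 0.16.

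G6PC1 did not differ past the threshold between media in insulin-stimulated cells (0.31 ± 0.34; edgeR adjusted p = 0.507), while IGFBP1 fell by 2.55, TAT by 2.28, KLF15 by 2.66 and PCK1 by 1.00. ALB, the main secreted protein of hepatocytes, was at -1.05 ± 0.18 and 17 of 23 hepatocyte identity genes were lower (17 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.00124, and adjusted p = 0.684 with an estimated correlation). The stromal median was 0.90, and without the 6 libraries the hepatocyte and stromal medians were -0.23 and 0.22, with 10 hepatocyte identity genes lower and 4 higher. HK2 (hexokinase 2) fell by 2.18, PLIN2 by 0.69 and INSR by 0.56.

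By edgeR, 2154 genes were higher and 4733 lower (31.3% higher), and without the 6 libraries 3236 and 3320. With averaged TMM factors the split was 2997 and 3936, and with DESeq2's size factors 3118 and 3846. Scaled to hepatocyte genes, which raised the median of all genes by 0.47, it was 5813 and 703, and with the 6 libraries also left out (a shift of 0.15) 4357 and 1506. The ribosome biogenesis, chaperone, ATF4, NRF2 and MAPK feedback lists stayed below 0 under that scaling, with medians of -0.38, -0.57, -0.21, -0.20 and -0.29. Within the 22 April and 11 April batches 1105 and 2890 genes were called, and with summed triplets 944.

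LEAP2 (ENSG00000164406) was weakly transcribed, at 1.78 ± 0.141 CPM in untreated and 1.1 ± 0.371 CPM in insulin-stimulated cells in normal medium, and at 1.3 ± 0.432 and 0.974 ± 0.14 CPM in insulin-resistant medium (SD, n = 9 each). In normal medium it fell with insulin by 0.69 on the log2 scale (SE 0.17; edgeR adjusted p = 0.00166), and an exact two-sided permutation test gave p = 0.000329 (adjusted p = 0.00132 over 4 comparisons). In insulin-resistant medium the log2 fold change of LEAP2 with insulin was -0.39 ± 0.18 (edgeR adjusted p = 0.181; exact permutation p = 0.0485, adjusted p = 0.0646). The insulin responses of LEAP2 in the media were not shown to differ by edgeR with batch in the model, at 0.30 ± 0.25 (edgeR adjusted p = 0.379), but the difference passed the threshold at 0.74 with surrogate variables and 0.77 scaled to hepatocyte genes. Insulin-resistant medium itself lowered LEAP2 in untreated cells by 0.47 (SE 0.17; edgeR adjusted p = 0.0456; exact permutation p = 0.00469, adjusted p = 0.00938). That call was lost at -0.50 to -0.40 without any 1 of untreated replicates 1 to 8 in normal medium, or of untreated replicates 4 to 9 or stimulated replicates 1 and 3 in insulin-resistant medium. In insulin-stimulated cells the medium effect on LEAP2 was -0.17 ± 0.18 (edgeR adjusted p = 0.498; exact permutation p = 0.476, adjusted p = 0.476).

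LEAP2 was at 1.07 to 2.13 CPM in the 6 libraries low in stromal transcripts and at 0.685 to 2.08 CPM in the other 30. Without the 6, its log2 fold change with insulin was -1.05 in normal medium (edgeR adjusted p = 3.23e-07) and 0.01 in insulin-resistant medium (edgeR adjusted p = 0.997). Their difference of 1.07 passed the threshold (edgeR adjusted p = 0.000166). Without the 6 the medium effect on LEAP2 was -0.82 in untreated cells (edgeR adjusted p = 1.67e-05) and 0.24 in stimulated cells (edgeR adjusted p = 0.18). Hepatocyte identity genes were lower in that fit too. Their median was -0.30 for insulin in normal medium and -0.31 for medium in untreated cells. These LEAP2 values are therefore not relative to hepatocyte genes, and part of each fall may be shared with them. Over all alternatives the adjusted p of LEAP2 by edgeR, limma or DESeq2 ran from 2.27e-07 to 0.413 for insulin in normal medium, from 0.071 to 1 for insulin in insulin-resistant medium and from 0.000166 to 0.885 for their difference. For the medium effect it ran from 1.67e-05 to 0.928 in untreated and from 0.0113 to 0.993 in stimulated cells. With triplets summed the insulin effect on LEAP2 in normal medium was -0.79 (edgeR adjusted p = 0.156) with all libraries and -1.06 (edgeR adjusted p = 0.0202) without the 2 triplets low in stromal transcripts. Within batches, exact permutation tests of LEAP2 for insulin in normal medium gave p = 0.0159 on 22 April (4 against 5 libraries), 0.333 on 11 April (2 against 2) and 0.6 on 24 May (3 against 2), with lower means under insulin in each. The smallest p these splits can give is 0.0159, 0.333 and 0.2, so the last 2 cannot reach 0.05. For insulin in insulin-resistant medium, exact tests within the 22 April and 11 April batches gave p = 0.686 and 0.143, where 0.0571 and 0.0714 are the smallest possible, so neither can reach 0.05. For the medium effect in untreated cells the exact permutation tests gave p = 0.0286, 1 and 0.1 for 22 April, 11 April and 24 May, where 0.0286, 0.333 and 0.1 are the smallest possible, so only 22 April can reach 0.05. The 24 May test in untreated cells sets a single triplet of each group against the other. That for insulin in normal medium sets a single untreated triplet against stimulated replicates 2 and 4, of which replicate 4 is 1 of the 6. The exact tests gave in stimulated cells p = 0.679 and 0.5 for 22 April and 11 April, where the smallest possible are 0.0357 and 0.0714. No insulin-stimulated library in insulin-resistant medium belongs to 24 May.

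**Figure D4:**
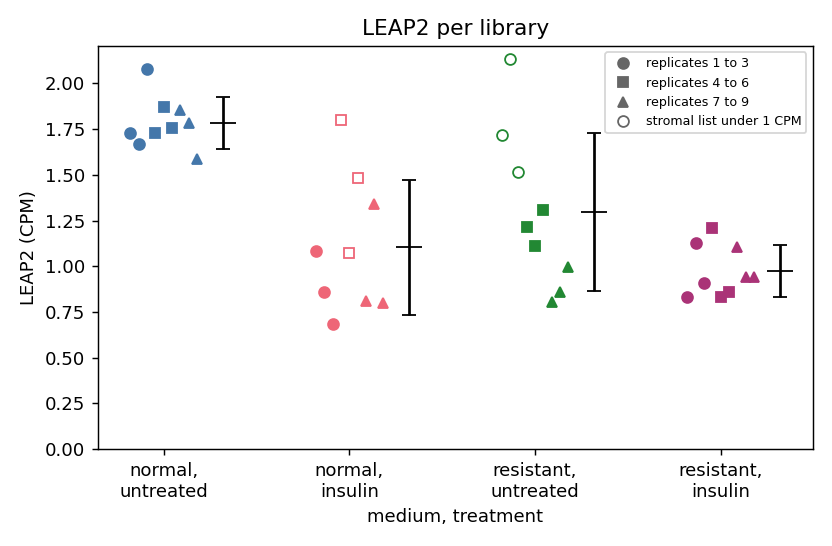
LEAP2 in CPM for each library, by medium and treatment; shapes mark replicate triplets, open symbols the 6 libraries with a stromal list median under 1 CPM, and bars the mean ± SD of 9 libraries. Untreated cells in normal medium lie between 1.58 and 2.08 CPM, and insulin-stimulated cells in insulin-resistant medium between 0.832 and 1.21 CPM.

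Many of the same genes were called for insulin in normal medium and for the medium in untreated cells, most of them in the same direction when all controls served both. Of the genes called in both, 1116 were higher in both and 430 lower in both, where independent lists would share 594.7 and 159, and 479 went opposite ways. Among them G6PC1, PCK1, BCL6 and FST fell and PLIN2 and ANGPTL8 rose in both. Across genes, which are not independent replicates, the fold changes had Pearson's r = 0.385 and Spearman's rho = 0.393, with a covariance of 0.1245. Without the 6 libraries low in stromal transcripts the balance turned. Then 542 genes were higher and 1248 lower in both, where independent lists would share 299.4 and 527.3. Another 563 went opposite ways, and r was 0.331. Both comparisons use the same untreated libraries. Simulated unchanged groups, with the controls also simulated and all libraries independent, gave a mean r of 0.492 and a mean covariance of 0.0669, with 0 shared calls. Since real libraries cluster by triplet, that 0 does not show how many calls triplets alone could share. When the 9 controls were split by triplets between the comparisons, 6 splits gave r from -0.041 to 0.331, covariances from -0.0216 to 0.1304 and 410 to 660 shared calls of the same direction against 57 to 496 of opposite direction. In the split with r = -0.041, 568 shared calls had the same and 496 the opposite direction. With the 6 libraries left out r ran from -0.111 to 0.334, with 822 to 1387 calls of the same and 247 to 1848 of opposite direction, and the split with the lowest r had 1154 calls of the same and 1848 of opposite direction. The size and direction of the agreement depended on which control triplet served which comparison, and the balance of higher and lower genes also on the 6 libraries. The insulin effects in normal and insulin-resistant medium had r = -0.129 and rho = -0.238 across genes, 0.099 and 0.033 without the 6 libraries, and shared no call, since none was made in insulin-resistant medium.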

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

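The tests of batch date and of mislabelling in this part were chosen only after the result was seen, while that of the hepatocyte level was set before. In a check for single samples far from the others, chance marks about 1 in 20 groups. The highest library total among insulin-stimulated cells in normal medium, 111.9M counts in replicate 2, was separated from the next by 0.494 of the group's range. The highest PCK1 level among insulin-stimulated cells in insulin-resistant medium was separated by 0.725 of its range.

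Among the key genes reported here, insulin effects that differed between media, as resistant minus normal log2 fold change in the test of the difference itself, were 4.68 for G6PC1, -1.41 for PLIN2, -1.25 for IGFBP1, -0.55 for SREBF1, -0.84 for FASN, -1.68 for FGF21 and -0.64 for ALB (edgeR adjusted p from 1.01e-08 for G6PC1 to 0.0492 for FGF21). Without the 6 libraries low in stromal transcripts, those of G6PC1 (5.54) and PLIN2 (-0.87) still passed the threshold, and those of IGFBP1 (-0.26), SREBF1 (-0.23), FASN (-0.08), FGF21 (-0.72) and ALB (0.29) did not. The difference of G6PC1 is bounded by its low level in untreated cells in insulin-resistant medium. FGF21 was near the floor in all groups, at 0.0161 to 0.464 CPM per library. With averaged TMM factors FGF21 (-1.61) and ALB (-0.57) did not pass. Without 1 library the call of FGF21 was lost at -1.71 to -1.33, except without untreated replicates 2, 5 or 8 or stimulated replicates 1, 3 or 9 in normal medium or untreated replicate 9 in insulin-resistant medium. That of ALB was lost at -0.65 to -0.40, except without untreated replicate 3 or stimulated replicates 1, 3, 7, 8 or 9 in normal medium.

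Stromal transcripts were high in 30 libraries and near 0 in 6, although all carry the label of 1 hepatoma line. COL1A1 was at 7170 to 35800 CPM against 0.742 to 1.6 CPM, and the median over the 12 listed markers was 0.0163 to 0.0788 CPM in the 6. The batch date as the cause is argued against, since the 6 libraries came from 3 dates, all that the labels give. An exchange of insulin labels in normal medium is argued against, since 0 of the 3 libraries had G6PC1 inside the range of the untreated arm (0.0928 to 0.225 CPM against 3.39 to 4.62 CPM). In insulin-resistant medium 1 of 3 lay inside the range of the other arm and the arms overlap, so that G6PC1 leaves an exchange open there, which would move the missing transcripts to the other arm without accounting for them. Stromal cells in the culture may be a source, although the labels name none, and over the 10 triplets with these transcripts the hepatocyte and stromal levels had Spearman's rho = -0.394 (permutation p = 0.265) and Pearson's r = -0.58 (permutation p = 0.0776), with r = -0.837 without the 2 triplets farthest from the median. The value of rho met the bound set beforehand for stromal cells, which asked for no p, but permuted levels often gave one as large, so that it stays undecided. A wrong label of the cells themselves was not tested. No biological explanation was tested, since the triplets are not a group of the design.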

How the results depend on the processing

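Fits without the 6 libraries low in stromal transcripts, with hepatocyte scaling, with averaged TMM factors, with triplets as the unit, and within the 11 April or 24 May batch were chosen only after the results were seen. The cause of each change below was not tested, except that fits within a batch or on summed triplets use fewer samples. Counts follow the order insulin in normal medium, difference of insulin effects, medium in untreated cells, medium in stimulated cells, unless named. Surrogate variables gave 10905, 9050, 7884 and 10722 genes, a minimum fold change of 1.2 gave 2907, 2868, 1485 and 3428, the 22 April batch 950, 4, 611 and 1105, and the 11 April batch 866, 636, 375 and 2890. Summed triplets gave 711, 5, 485 and 944, and 1096, 76, 610 and 925 without the 2 triplets low in stromal transcripts. A triplet as random block in limma gave 1997, 597, 692 and 2235, and 2350, 580, 1448 and 2459 without the 6 libraries. The 24 May batch gave 1808 for medium in untreated cells, where it sets a single triplet of each group against the other. It holds no stimulated library in insulin-resistant medium, so 3 comparisons have no value there. Without that batch insulin in normal medium gave 3454 and the difference 3040. The difference gave 2100 scaled to hepatocyte genes and 2897 without the 6 libraries and the batch term. Hepatocyte scaling without the 6 gave 11636 for insulin in normal medium and 13001 for medium in untreated cells. For insulin in insulin-resistant medium, 0 with edgeR became 85 with DESeq2, 2063 without the batch term, 4481 and 4875 with a plate-set term in place of or beside it, 3065 with surrogate variables and 4012 with only its own groups.

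With the replicate number as a block beside the batch, insulin in insulin-resistant medium gave 2674 genes, and no other count moved by over 1.5 times. Of the values of single genes compared, 6 gained and 2 lost their call under the block, and none turned direction. The numbers do not pair the samples across all groups. Correlations of same-numbered libraries exceeded 0.1 in 8 of 9 pairs of untreated and stimulated cells in normal medium. In insulin-resistant medium they did in 7 of 9 such pairs, with a median of 0.161. They did so in only 3 of 9 pairs of stimulated cells in normal and untreated cells in insulin-resistant medium. There each pair of replicates 1 to 6 held 1 of the 6 libraries low in stromal transcripts, with correlations of -0.936 to -0.479. That comparison therefore cannot tell pairing from the place of the 6 libraries. Untreated cells in normal and stimulated cells in insulin-resistant medium hold none of the 6. Of their pairs 6 of 9 exceeded 0.1, and the lowest was -0.493.

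LEAP2 under insulin in normal medium lost its call at -0.59 on 11 April, -0.46 on 24 May, -0.79 with summed triplets and -0.72 with a triplet as random block, and the adjusted p by edgeR, limma or DESeq2 ran from 2.27e-07 to 0.413 over all alternatives. The difference of LEAP2 effects passed the threshold at 0.74 with surrogate variables, 1.07 without the 6 libraries (also with only its own groups), 0.92 without them and the batch term, 0.77 scaled to hepatocyte genes and 0.71 with both changes. The medium effect on LEAP2 in untreated cells lost its call at -0.49 with no filter, -0.47 with only its groups, with a minimum fold change and with summed triplets, -0.43 without 24 May, -0.63 on 22 April and with a triplet as random block, -0.09 on 11 April, -0.57 on 24 May and -0.74 with summed triplets less 2 (adjusted p from 1.67e-05 to 0.928 over all alternatives). In stimulated cells it turned from -0.17 to 0.4 scaled to hepatocyte genes and 0.38 with the 6 also left out, both past the threshold. Short of it, it turned to 0.05 with surrogate variables, 0.01 with only its groups, 0.16 on 22 April and with summed triplets less 2, 0.24 without the 6 (also with only its groups), 0.14 also without batch, and 0.28 with a triplet as random block and the 6 left out. LEAP2 under insulin in insulin-resistant medium turned from -0.39 to 0.01 without the 6, 0.16 also with only its groups, 0.09 scaled to hepatocyte genes, 0.07 with both changes, and 0.02 with a triplet as random block and the 6 left out. The difference of LEAP2 effects turned to -0.13 on 11 April. LEAP2 has no value under the filter of 5 CPM. Of the other values of single genes, over all alternatives but those that leave out 1 library, 2588 kept their direction and side of the threshold, 244 lost their call, 45 gained one and 29 turned. ALB under insulin in normal medium turned from 0.15 to -0.3 without the 6 (also with a triplet as random block), -0.36 also without batch, -0.26 with only its groups, -0.32 with summed triplets less 2, -0.11 with surrogate variables, -0.15 on 22 April, and just under 0 (0 when rounded) without 24 May or with the filter of 5 CPM. FASN there turned to -0.06 without the 6 and batch and -0.01 with summed triplets less 2, and IGF1R to 0.08 scaled to hepatocyte genes without the 6. Under insulin in insulin-resistant medium G6PC1 turned from -0.41 to 0.01 without the 6, 0.03 scaled to hepatocyte genes, 0.06 with both changes, 0 with summed triplets less 2, 0.04 with a triplet as random block and 0.16 with the 6 also left out. IGFBP1 there turned to 0.01 with only its groups and the 6 left out, 0.05 with hepatocyte scaling and the 6 left out, and 0.05 with a triplet as random block and the 6 left out. PLIN2 turned to 0.05 with only its groups and the 6 left out, 0.15 scaled to hepatocyte genes and 0.02 with the 6 also left out. ALB in the difference turned to 0.29 without the 6, with all or only its groups, 0.16 also without batch, 0.09 with summed triplets less 2, and 0.35 with a triplet as random block and the 6 left out. Of these values, ALB in normal medium without the 6, with or without batch, was past the threshold after turning.

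With an estimated correlation 0 lists were called for 4 comparisons and 2 for medium in untreated cells, with or without the 6 libraries; without the 6 the preset one called 13 for insulin in normal medium and 9 for medium in untreated cells. Genes called in the same direction for insulin in both media were 509 without batch, with 388 in opposite directions, and 17 with DESeq2, with 17 opposite. For insulin and medium they were 648 without 24 May, 9430 with the 6 left out and hepatocyte scaling, and 488 with a triplet as random block and the 6 left out.

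Leaving out 1 library gave 5135 to 6465 genes for insulin in normal medium, 3990 to 6024 for the difference, 3366 to 4250 and 5745 to 7390 for medium in untreated and stimulated cells, and 0 to 2008 for insulin in insulin-resistant medium, with 2008 without untreated replicate 7 and 965 without untreated replicate 9. LEAP2 ran from -0.95 to -0.63, from -0.48 to -0.21, from 0.23 to 0.6, from -0.62 to -0.4 and from -0.24 to 0.01 for insulin in normal and insulin-resistant medium, their difference, and medium in untreated and stimulated cells. The last was above 0 without stimulated replicate 4 or 6 in normal medium. ALB under insulin in normal medium ran from -0.07 to 0.22, and was below 0 without untreated replicates 8 or 9 or stimulated replicates 4, 5 or 6. The LEAP2 call for medium in untreated cells was lost without any of untreated replicates 1 to 8 in normal medium, untreated replicates 4 to 9 or stimulated replicates 1 and 3 in insulin-resistant medium. Leaving out a library can also change the TMM reference: over the 36 references the shift against the default ran from -0.12 to 0 for insulin in normal medium, from -0.04 to 0.11 for the difference, and from 0 to 0.11 for medium in stimulated cells. Depth limits LEAP2, with 40 to 222 counts per library, and G6PC1 where it is low, with 1 to 17. It also limits FGF21, at a mean of 0.113 CPM over all libraries.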

Other observations

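The tests of date, of the 6 libraries, of imprecision and of a prior effect of the medium were chosen only after the result was seen, while the stromal level and the splits of the samples were set before. IRS2, an adaptor of the insulin receptor, was at 0 to 0.0928 CPM in the 6 libraries low in stromal transcripts and at 13.1 to 53 CPM in the other 30. Leukocyte markers had medians of -0.65 for insulin in normal medium (camera adjusted p = 0.0517) and 0.88 for the difference between media (camera adjusted p = 0.0748), and endothelial markers of -0.64 and 1.04 (camera adjusted p = 0.261 and 0.437).

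Of 20 p53 targets 8 rose with insulin in normal medium (8 adjusted over the list alone; camera adjusted p = 0.0515), and of 22 respiratory chain genes 8 rose (8 adjusted over the list alone; camera adjusted p = 0.0961), with a median of 0.06 that turned to -0.01 with averaged TMM factors. Without the 6 libraries 6 p53 targets were higher and 2 lower (camera adjusted p = 0.0238, and adjusted p = 0.362 with an estimated correlation), and 2 respiratory chain genes were higher (camera adjusted p = 0.542). The insulin receptor pathway list had 10 of 24 members higher (10 adjusted over the list alone; camera adjusted p = 0.224), the hypoxia list 4 of 20 higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.769; median -0.07, and 0.05 scaled to hepatocyte genes), and the glycolysis list 2 of 23 higher and 4 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.103). The fatty acid synthesis list had 5 of 20 higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.769), with a median of 0.02 that turned to -0.05 with averaged TMM factors. With the 6 libraries left out it had 3 members higher and 9 lower, with a median of -0.20 (camera adjusted p = 0.00622, and adjusted p = 0.314 with an estimated correlation). The insulin receptor pathway list then had 7 higher and 4 lower (camera adjusted p = 0.22), the hypoxia list 3 and 2, and the glycolysis list 2 and 6. In insulin-stimulated cells the medium went with 13 of 25 secreted liver proteins lower and 1 higher (15 and 1 adjusted over the list alone; camera adjusted p = 0.00736, and adjusted p = 0.377 with an estimated correlation), a median of -0.51 that turned to 0.02 when scaled to hepatocyte genes, and without the 6 libraries 11 were lower and 2 higher, with a median of -0.08.

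Libraries clustered by replicate triplet, which explained 94.7% of the variance within groups, with the exceptions given for stimulated cells. Batch date as the whole cause is argued against, since it explained 21.7%. A stromal share that differs between triplets stays open. The 94.7% is on log2(CPM + 1) over the more highly expressed of the genes tested. On the same scale over all 17983 genes tested, the triplet alone explained 93.3%. There the stromal level alone explained 71.2%, and beyond it the triplet explained 22.6%, which is 78.6% of what was left. The bound set beforehand for this cause named the variance within groups, a share computed only after the other, and 22.6% met it. The bound against it named no share, and 78.6% lay beyond it. A shared culture or handling of each triplet may be a source and was not tested, since the labels do not say what the sets are.

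Insulin called no gene in insulin-resistant medium by edgeR, with 4490 genes at an unadjusted p under 0.05 and 85 called by DESeq2. The 6 libraries low in stromal transcripts are argued against as the whole cause, since without them 0 genes were called, also without the batch term. That fit could miss small effects. It leaves 6 untreated libraries in this medium, 3 of them from 24 May, a date with no stimulated library there. With 30 simulated independent libraries, 55.2% of genes changed 1.5-fold were called in this comparison. Imprecision alone is argued against, since among genes moved over 2-fold by insulin in normal medium the median ratio of the log2 fold changes, resistant to normal, was -0.029 with 36 libraries (quartiles -0.26 and 0.297) and 0.029 with 30 (-0.082 and 0.126). A medium that had already moved these genes to their insulin-stimulated level is argued against as the whole cause. Its log2 fold change was at most 0.377 of that of insulin in the median over splits of the controls. Single genes did near or pass that level. The medium moved G6PC1 by -4.37 (insulin -5.09), FST by -2.30 (-1.88), PCK1 by -1.30 (-0.87), BCL6 by -0.96 (-0.58) and ANGPTL8 by 1.91 (2.22). The ribosome biogenesis and chaperone lists did not, with medians of 0.13 and 0.08 against 0.88 and 1.04 for insulin. A weaker response in this medium is therefore a hypothesis that may hold for many genes, with the triplet structure left open and with no label that says whether untreated cells there were still in 1 nM insulin, and the count of 0 itself changed with the model, to 4012 with only the groups compared.

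Other splits of the libraries were fitted with only the groups compared, except for the difference, which used all 36. The real split was the 1 of 50 random splits with as many genes for insulin in normal medium (4691, highest other 3837), insulin in insulin-resistant medium (4012, highest other 0), the difference (5352, highest other 2817), medium in untreated cells (3984, highest other 0) and medium in stimulated cells (4670, highest other 271). Chance is excluded there if libraries vary independently, which the triplets speak against. Splits of whole triplets number 10, so a share under 0.05 is not possible. Their highest other counts were 4598 for insulin in normal medium, 5359 for insulin in insulin-resistant medium, 10612 for medium in untreated cells and 1207 for medium in stimulated cells. For insulin in insulin-resistant medium and for medium in untreated cells 3 of 10 splits gave as many genes as the real one, and 10612 against 3984 points to a structure of the samples.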
